A study of Rhodococcus erythropolis PR4 with 4 samples.

How the data were processed

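Total RNA of R. erythropolis PR4 cultures was depleted of ribosomal RNA and sequenced as 50-base reads on a SOLiD 5500xl instrument, per the labels' protocols. Cultures of 5 L at 25 °C and pH 7.5, with 20% oxygen saturation and 0.5 g/L of an amino acid mix, received 30 g/L sodium acetate, 1% (v/v) hexadecane or diesel oil. Stirring started at 100 rpm for acetate, per the labels. Groups were taken from the labels, and each expression column was matched to a library by its name.

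Per the file headers, reads were trimmed and the authors deposited normalized expression values; each column has the same sum and TPM times coding length gives whole reads, so the deposited values were treated as TPM. The aligner, genome build and counting rules are not given in the sources used here. The authors also deposited signed fold ratios between pairs of libraries; these equalled the ratio of the second to the first library's TPM within a relative tolerance of 0.001 wherever both were above 0, and were not used further. A second deposited table lacked hexadecane replicate 2 and held identical values in all 19533 cells compared. Rows carry locus tags and product names; coordinates and symbols were not used here.

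The design fixed before the data were examined called for a count-based test if the tables held counts, and otherwise for limma on log2(value + 1). The tables held TPM, so limma 3.58.1 (R 4.3.3) was fitted with a trend to log2(TPM + 1) of all 6511 genes and all 4 libraries, with Benjamini-Hochberg adjustment at 0.05 and no filter. Adding 1 to the TPM shrinks the fold change of low genes. The raised low values of hexadecane replicate 2 and diesel oil can enlarge it in comparisons with acetate, so folds of low genes are not conservative. The hexadecane pair left 1 residual degree of freedom, and the lone acetate and diesel oil libraries were assumed to vary as that pair does. SE is the moderated standard error.

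TPM times coding length came out as whole multiples of a step per library for all 6437 coding genes (tolerance 0.001 of a step), which gave the number of reads per gene, with medians of 297, 247, 193 and 423 reads for acetate, hexadecane replicates 1 and 2 and diesel oil. A gene with 0 reads was bounded at 3 reads in its library; such bounds cover counting error only. A chi-square test of the reads of the hexadecane libraries gave 121 per degree of freedom, so they were counted as 2 libraries. No pair of genes was treated as sharing reads, although 16 coding genes have a translation identical to that of another and their values are uncertain.

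The fitted spread did not hold for every gene. The prior degrees of freedom were infinite without a filter and 4.12 with 20 TPM required in a library. In the unfiltered fit 2.32% of genes had a hexadecane pair farther apart than the 0.1% point of the fitted distribution. A self-test simulated hexadecane vs acetate on 6511 genes with 200 changed. The changed genes were drawn from coding genes with a mean of 20 TPM or more, so recovery was not measured for lower genes. The spread followed the fit but was capped at its value for the gene of middle expression. That log2 SD was 0.348, against a fitted 0.620 at the 25th percentile of expression. With this capped spread, 94.0% of 4-fold changes were recovered and 2.13% of calls were false. A first version of this test, which set low simulated values to 0, recovered fewer changes, failed its bound on recovery and was replaced. That bound was then dropped, and only a bound on the error of the fold was kept. With a spread that differs between genes and no floors, the unfiltered fit recovered 40.3% of 4-fold changes, and 13.0% of its calls were false. With the 20 TPM filter these were 34.8% and 11.6%. With a spread that differs between genes and the libraries' own floors, the unfiltered fit recovered 83.6% of 4-fold and 98.5% of 16-fold changes, and 42.2% of its calls were false. With the 20 TPM filter, on 4274 genes, these were 57.6%, 84.8% and 21.1%. Filters at 5, 10, 20 and 50 TPM were tried after seeing the data, and the fit at 20 TPM is given beside the unfiltered one. Simulated spreads are assumptions, so the false shares are not error rates of the real calls.

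Gene lists (22) were fixed before the data were examined and matched by product name. For each list and comparison the number called, the number adjusted over the list alone, the median log2 fold change and its percentile among 10000 random lists matched on deciles of mean expression were computed. Percentiles describe these libraries and are not tests. Name matching admits members that do other work, such as isopropylmalate synthase in the glyoxylate list and siderophore enzymes in the aromatic list.

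Named genes followed a rule fixed beforehand: per comparison, the 8 largest fold changes in each direction among called genes with 5 TPM or more, a named product and, where hexadecane was compared, both of its libraries on the same side; the 2 called members of each list with the largest change, or the highest-expressed member if none was called; all alkane monooxygenase and rubredoxin genes; and 1 hypothetical protein per direction. This gave 57, 57 and 60 genes, of which 28, 27 and 10 also passed with the filter at 20 TPM. Some were left out for length, not strictly in order of fold, and among them are genes whose call was lost with the filter. Runs of consecutive genes, pREL1_0283, pREL1_0260 and the genes named in the closing section under other headings were chosen after their values were seen.

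Alternatives fixed beforehand were median-of-ratios scaling, a pseudocount of 0.1, at least 50 recovered reads in a library, RNA genes left out, an adjusted p of 0.01, each hexadecane library left out, and ribosomal proteins left out of the random lists. The filter at 20 TPM, subtraction of each library's 5th percentile with values under 0 set to 0, alone and with that filter, a spread without trend and limma-voom on recovered reads, and for silent genes the spread without the highest of them, were added after seeing the data. Lists of the observed sizes, with and without the filter and in opposite directions, in the simulation of unchanged groups, which drew 4 libraries per set from each gene's mean and fitted spread, were also chosen then. Tables and figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and proteins were compared with BLAST 2.17.0.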

Results

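Rhodococcus erythropolis PR4, an alkane-degrading actinobacterium, was grown in a fermenter on sodium acetate, on n-hexadecane or on diesel oil, and RNA was taken in late exponential growth. There were 4 RNA-seq libraries, 1 from acetate (labelled the control), 2 from hexadecane and 1 from diesel oil. The acetate medium held 30 g/L sodium acetate and was sampled at 31 h, the hydrocarbon cultures at 21 h, so carbon source, salt and hour cannot be told apart in comparisons with acetate. Values were TPM for 6511 genes. The reads on coding genes, recovered from the TPM, numbered 12020879 for acetate, 10339516 and 6709294 for hexadecane replicates 1 and 2, and 14175526 for diesel oil. The labels do not say whether the hexadecane libraries came from separate cultures, so every p-value rests only on differences between these 2 libraries, which may be technical. In the fit without a filter the prior degrees of freedom were infinite. A gene's p-value there used the spread fitted for its expression level and not that of its own pair. A gene whose hexadecane pair lay far apart could therefore be called. The acetate and diesel oil libraries had no replicate.

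Genes of the plasmid pREL1 held 2.29% of TPM on acetate, 5.75% and 5.95% on hexadecane and 8.77% on diesel oil. Genes of pREC1 held 0.741% on acetate and 0.375%, 0.388% and 0.428% in the hydrocarbon libraries. Ribosomal RNA, which had been depleted before sequencing, held 2.17%, 3.97%, 9.99% and 5.15% in the same order, and transfer RNA 8.40%, 7.72%, 3.07% and 2.82%. The hexadecane libraries correlated across genes, which are not independent replicates, at Pearson r = 0.952 and Spearman rho = 0.952, with 81.0% of genes within 2-fold. The SD of their log2 ratio was 0.805, against 0.799 between hexadecane replicate 2 and diesel oil. Over genes with a mean of 20 TPM or more in the pair compared, it was 0.718 for the hexadecane pair, with 92.1% within 2-fold, and 0.892 with 81.3% for hexadecane replicate 2 and diesel oil.

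Low genes separated the libraries another way. The 5th percentile of coding genes was 0.911 TPM on acetate, 0.968 in hexadecane replicate 1, 3.84 in replicate 2 and 4.22 on diesel oil. The number of called genes changed with the treatment of low genes. Without a filter, limma called 685 genes in hexadecane vs acetate, 860 in diesel oil vs acetate and 639 in diesel oil vs hexadecane. With 20 TPM required in a library it called 130, 160 and 32. With a spread fitted without trend it called 0 in each (unadjusted p under 0.05 in 542, 775 and 514). After the 5th percentile of each library was subtracted it also called 0 (unadjusted p under 0.05 in 919, 1099 and 996), but the subtraction left 158 genes at 0 in both hexadecane libraries. Subtraction together with the filter called 34, 0 and 0 (unadjusted p under 0.05 in 783, 911 and 795). Below, rose and fell refer to the fit without a filter, and the SE and adjusted p beside a gene are both from limma with the filter at 20 TPM, which was chosen after seeing the data. Percentiles place the median log2 fold change of a gene list among 10000 random lists matched on expression, as a description of these libraries. A list's median under median-of-ratios scaling stands beside it, as other scaling, where its sign turned.

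**Figure D1:**
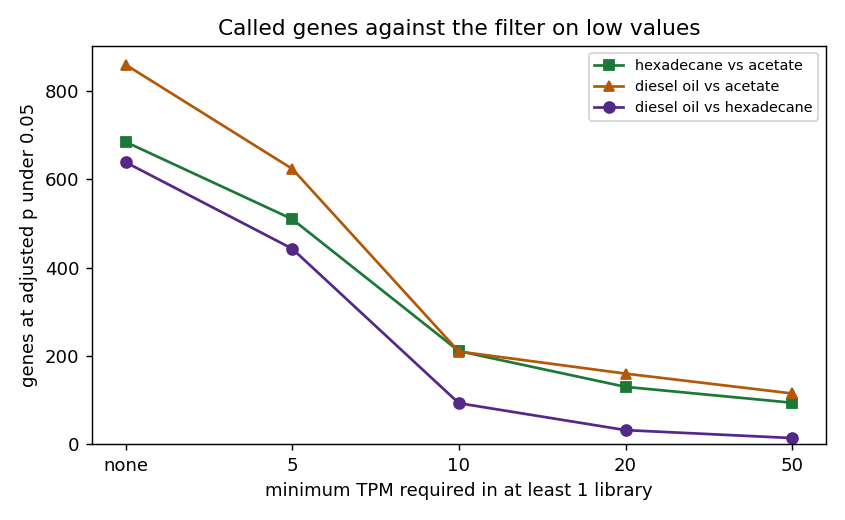
Number of genes with adjusted p under 0.05 (limma, vertical axis) for each of the 3 comparisons, against the minimum TPM that a gene had to reach in at least 1 library (horizontal axis). The counts fall from 685, 860 and 639 without a filter to 94, 115 and 14 at 50 TPM.

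The comparison of hexadecane with acetate asked which genes follow growth on a pure alkane. Consecutive genes for alkane hydroxylation rose. Alkane-1-monooxygenase RER_07460, which adds oxygen to the alkane chain, rose from 13.4 TPM on acetate to 4863 ± 51.4 TPM (SD, n = 2) on hexadecane, a log2 fold change of 8.40 (SE 0.33, adjusted p = 0.00152). The electron carriers beside it rose too, rubredoxin RER_07470 from 7.08 to 3935 ± 121 TPM and rubredoxin RER_07480 from 3.15 to 3882 ± 496 TPM. Rubredoxin reductase RER_07490 rose from 3.56 to 2244 ± 339 TPM, TetR family regulator RER_07500 from 20.0 to 1658 ± 181 TPM and hypothetical protein RER_07520 from 10.5 to 1381 ± 227 TPM. Alkane-1-monooxygenase RER_21620 rose to a lower level, from 9.27 to 169.9 ± 20.2 TPM (log2 fold change 4.05, SE 0.28, adjusted p = 0.00597). Rubredoxins RER_21630 and RER_21640 rose to 64.3 ± 0.0742 and 80.6 ± 4.01 TPM. Alkane-1-monooxygenase genes RER_54580, at 58.9 and 76.4 ± 7.00 TPM, and RER_24030, at 18.9 and 11.7 ± 1.59 TPM, did not pass the test. Of 34 alkane oxidation genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone, 9 and 0 of 21 tested with the filter), with a median of 0.72 at percentile 99.99. The 10 include the neighbouring genes RER_07460 to RER_07490 and RER_21620 to RER_21640 named above.

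**Figure D2:**
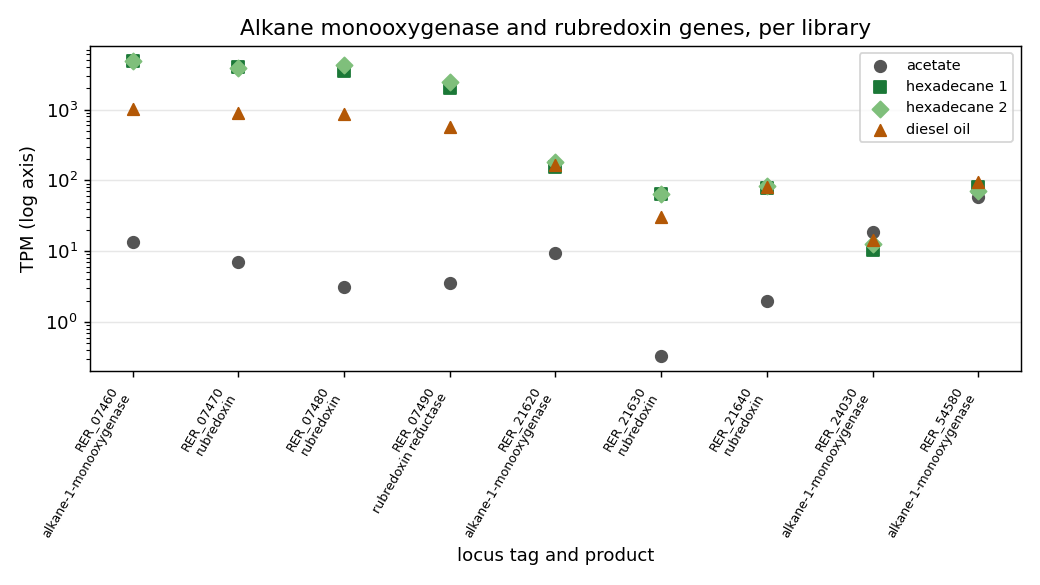
TPM (vertical log axis) of each alkane monooxygenase and rubredoxin gene (horizontal axis, locus tag and product), with 1 point per library. The acetate points of RER_07460 to RER_07490 lie at 13.4 TPM or lower, and their hexadecane points at 2004 TPM or higher.

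On pREL1, fatty-acid--CoA ligase pREL1_0286, of an enzyme class that activates fatty acids for breakdown, rose from 99.0 to 3510.0 ± 29.1 TPM (SD, n = 2, adjusted p = 0.00597). Near it, cytochrome P450 pREL1_0283 rose from 408 TPM to 4806 and 6229 TPM, and transposase pREL1_0288 from 17.7 to 600.3 ± 60.2 TPM. Of 77 mobile elements genes, 15 rose and 5 fell (19 and 5 adjusted over the list alone, 5 and 0 of 58 tested with the filter), with a median of 0.70 at percentile 100. The 5 called with the filter were all transposases of the consecutive run pREL1_0282 to pREL1_0291, which holds the cytochrome P450 and the ligase. On the chromosome, oxidoreductase RER_55960 rose from 5.12 to 720.4 ± 105 TPM, and drug resistance efflux protein RER_37360 from 11.6 to 301 ± 96.4 TPM. Of 58 multidrug and lipid exporters genes, 4 rose and 2 fell (the same adjusted over the list alone, 1 and 1 of 30 tested with the filter), with a median of 0.48 at percentile 99.01. Of 196 beta-oxidation genes, 19 rose and 17 fell (20 and 18 adjusted over the list alone, 6 and 4 of 104 tested with the filter), with a median of 0.15 at percentile 20.9.

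Iron-siderophore binding proteins RER_10280 and RER_27020, which belong to iron uptake, rose from 2.16 and 24.5 TPM to 34.7 ± 11.8 and 184 ± 122 TPM. Their calls were lost with the filter (adjusted p = 0.0714 and 0.104). Of 41 iron uptake and storage genes, 9 rose and 0 fell (10 and 0 adjusted over the list alone, 1 and 0 of 27 tested with the filter), with a median of 0.89 at percentile 100. These 9 iron genes include the neighbouring siderophore genes of the run RER_26950 to RER_27050, which holds RER_27020. Mce family protein RER_47560, of a family of lipid transporters, rose from 8.47 to 56.2 ± 3.40 TPM. Of 47 steroid breakdown and Mce transporters genes, 9 rose and 0 fell (the same adjusted over the list alone, 2 and 0 of 12 tested with the filter), with a median of 0.88 at percentile 99.99. The 9 include the neighbouring Mce family genes of the run RER_17240 to RER_17300, where 0 genes were called with the filter. They also include RER_07540, the last gene of the run that holds alkane-1-monooxygenase RER_07460. Of 59 ribosomal proteins genes, 5 rose and 1 fell (the same adjusted over the list alone, 0 and 0 of 58 tested with the filter), with a median of 0.55 at percentile 100. The gene that fell was RER_18770, for 50S ribosomal protein L36, from 23079 to 5294 ± 2211 TPM, a call lost with the filter (adjusted p = 0.137).

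Fatty-acid synthase I RER_38730, the multidomain enzyme that builds fatty acids, fell from 822 to 10.1 ± 5.97 TPM (SD, n = 2), a log2 fold change of -6.32 (SE 0.51, adjusted p = 0.00857). Its neighbour RER_38720, a holo-[acyl-carrier-protein] synthase, fell from 998 to 36.5 ± 6.27 TPM. Of 44 fatty acid and mycolic acid synthesis genes, 1 rose and 3 fell (the same adjusted over the list alone, 0 and 2 of 31 tested with the filter), with a median of 0.26 at percentile 87.3. Proline/betaine transporter RER_37810 fell from 909 to 30.5 ± 19.5 TPM and ectoine synthase RER_37870 from 1309 to 159.9 ± 69.1 TPM. Both act on compatible solutes, which balance osmotic pressure. Of 10 trehalose and compatible solutes genes, 0 rose and 4 fell (the same adjusted over the list alone, 0 and 2 of 8 tested with the filter), with a median of -0.63 at percentile 0.47.

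NAD-dependent glutamate dehydrogenase RER_51250 fell from 193 to 5.89 ± 0.300 TPM (SD, n = 2), aspartate ammonia-lyase RER_56380 from 163 to 7.95 ± 3.22 TPM and hypothetical protein RER_51270 from 331 to 3.10 ± 0.729 TPM. Of 37 nitrogen assimilation genes, 0 rose and 5 fell (0 and 6 adjusted over the list alone, 0 and 1 of 23 tested with the filter), with a median of 0.01 (-0.0825 with other scaling) at percentile 10.3. Acetate--CoA ligase RER_04960, which activates acetate, fell from 209.6 to 35.3 ± 5.96 TPM (adjusted p = 0.0213). Acetate permease RER_45270 fell from 64.1 to 5.28 ± 4.80 TPM, a call lost with the filter (adjusted p = 0.0947). Of 6 acetate activation genes, 0 rose and 4 fell (0 and 5 adjusted over the list alone, 0 and 1 of 6 tested with the filter), with a median of -1.66 at percentile 0. Alcohol dehydrogenase RER_23910 fell from 458 to 38.7 ± 5.70 TPM. Of 57 alcohol and aldehyde dehydrogenases genes, 1 rose and 5 fell (the same adjusted over the list alone, 0 and 1 of 26 tested with the filter), with a median of 0.34 at percentile 76.9. In the tricarboxylic acid cycle, 2-oxoglutarate dehydrogenase E1 RER_41220 fell from 1239 to 342 ± 1.90 TPM, a call lost with the filter (adjusted p = 0.0559). Of 16 tricarboxylic acid cycle genes, 0 rose and 3 fell (0 and 4 adjusted over the list alone, 0 and 0 of 14 tested with the filter), with a median of -0.67 at percentile 0.06. Isocitrate lyase RER_15740 of the glyoxylate shunt, at 3912 and 2511 ± 880.1 TPM, did not pass. Of 10 glyoxylate shunt and gluconeogenesis genes, 0 rose and 0 fell (the same adjusted over the list alone, limma, with 2 at an unadjusted p under 0.05), with a median of -0.51 at percentile 1.17. Of 9 propionyl-CoA metabolism genes, 0 rose and 2 fell (the same adjusted over the list alone, 0 and 0 of 6 tested with the filter), with a median of -0.37 at percentile 1.91.

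Of 33 sulfur assimilation genes, 4 rose and 0 fell (the same adjusted over the list alone, 0 and 0 of 18 tested with the filter), with a median of 0.34 at percentile 53.1. Of 27 oxidative stress genes, 3 rose and 1 fell (3 and 2 adjusted over the list alone, 0 and 0 of 22 tested with the filter), with a median of 0.08 (-0.0163 with other scaling) at percentile 69.2. Of 24 sigma factor genes, 1 rose and 4 fell (2 and 4 adjusted over the list alone, 0 and 0 of 20 tested with the filter), with a median of -0.13 at percentile 24.1. Of 27 chaperones and proteases genes, 1 rose and 1 fell (the same adjusted over the list alone, 0 and 0 of 26 tested with the filter), with a median of -0.15 at percentile 28.7. Of 48 ATP synthase and respiratory chain genes, 3 rose and 2 fell (the same adjusted over the list alone, 1 and 0 of 43 tested with the filter), with a median of 0.05 (-0.0396 with other scaling) at percentile 37.7. Of 32 aromatic compound breakdown genes, 2 rose and 2 fell (the same adjusted over the list alone, 0 and 0 of 12 tested with the filter), with a median of 0.10 at percentile 15.1. The 2 that rose were a dihydroxybenzoate dehydrogenase and ligase of the run RER_26950 to RER_27050, siderophore enzymes admitted by name matching. Of 6 triacylglycerol and wax ester genes, 1 rose and 0 fell (the same adjusted over the list alone, 0 and 0 of 3 tested with the filter), with a median of 0.22 at percentile 57.6. Sulfate ABC transporter permease RER_37550 was at 12.3 TPM on acetate, 16.0 TPM in hexadecane replicate 1 and 114 TPM in replicate 2, a call lost with the filter (adjusted p = 0.446).

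In limma on log2(TPM + 1), 685 genes passed an adjusted p of 0.05, 336 higher and 349 lower, against 66 higher and 64 lower with the filter and 73 higher and 123 lower with limma-voom on recovered reads. In 287 genes the fitted difference was 4-fold or more, 152 higher and 135 lower (148 and 154 under median-of-ratios scaling, 165 and 208 with the floor subtracted). Without hexadecane replicate 1 these were 389 and 125, and without replicate 2 106 and 176. The median log2 fold change of all genes was 0.12, against 0.23 without hexadecane replicate 1 and -0.046 without replicate 2, and -0.027 with the filter.

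Diesel oil, a mixture of hydrocarbons, was compared with acetate, 1 library against 1, so the difference has no replicate check of its own. The 5th percentile of these libraries also differed, at 0.911 TPM on acetate and 4.22 TPM on diesel oil. An effect of the libraries on the calls cannot be told apart from one of carbon source in this comparison. Alkane-1-monooxygenase RER_07460 rose from 13.4 to 1007 TPM (log2 fold change 6.13, SE 0.39, adjusted p = 0.00794). Rubredoxin RER_07480 rose from 3.15 to 857 TPM and alkane-1-monooxygenase RER_21620 from 9.27 to 164 TPM. Of 34 alkane oxidation genes, 13 rose and 1 fell (the same adjusted over the list alone, 9 and 0 of 21 tested with the filter), with a median of 1.26 at percentile 99.99. The 13 include the same neighbouring genes, RER_07460 to RER_07490 and RER_21620 to RER_21640. Fatty-acid--CoA ligase pREL1_0286 rose from 99.0 to 2673 TPM. Another pREL1 run, pREL1_0256 to pREL1_0263, had a median of 451 TPM on acetate and 3784 TPM on diesel oil. It holds a fatty-acid--CoA ligase, an alcohol and an aldehyde dehydrogenase, a ferredoxin and cytochrome P450 pREL1_0260, which rose from 536 to 4965 TPM. Drug resistance efflux proteins pREL1_0242 and RER_37360 rose from 41.9 and 11.6 TPM to 1159.6 and 682 TPM (adjusted p = 0.00794 and 0.00932). Of 58 multidrug and lipid exporters genes, 5 rose and 3 fell (the same adjusted over the list alone, 2 and 1 of 30 tested with the filter), with a median of 0.78 at percentile 83.8.

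A run of 13 consecutive genes, RER_13170 to RER_13290, with glycosyltransferases and a polysaccharide biosynthesis protein, rose from a median of 8.97 to 349.6 TPM, and 13 of them passed with the filter. Its medians in the hexadecane libraries were 45.7 and 88.3 TPM. Valine dehydrogenase RER_40180, of branched-chain amino acid metabolism, rose from 2.60 to 319 TPM. Peroxidase RER_11620 rose from 6.06 to 172 TPM beside hypothetical protein RER_11630, which rose from 0.846 to 211 TPM. Subunits A and C of a potassium-transporting ATPase, a potassium uptake system, rose, RER_37260 from 0.574 to 115 TPM and RER_37240 from 0.465 to 121 TPM. Their calls were lost with the filter (adjusted p = 0.117 and 0.105), and the hexadecane libraries held RER_37260 at 4.52 and 50.8 TPM. KdpF protein RER_37270 had 0 reads on acetate, which allows up to 1.83 TPM at 3 reads in that library. At 115 TPM on diesel oil it was at least 62.5-fold higher, by counting error only. Its call was also lost with the filter (adjusted p = 0.132), and the hexadecane libraries held it at 3.47 and 64.2 TPM.

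List medians in this comparison stand beside a median of 0.45 over all genes, and median-of-ratios scaling moved them by -0.48 to -0.39. The random lists matched on expression, which the percentiles use, had medians from 0.03 for ribosomal proteins to 1.08 for steroid breakdown and Mce transporters. For sulfur assimilation theirs was 0.83. Of 27 oxidative stress genes, 8 rose and 0 fell (the same adjusted over the list alone, 3 and 0 of 22 tested with the filter), with a median of 0.75 at percentile 99.56. Catalase-peroxidase RER_12250, which breaks down hydrogen peroxide, rose from 17.7 to 135 TPM. Of 196 beta-oxidation genes, 25 rose and 10 fell (26 and 10 adjusted over the list alone, 10 and 2 of 104 tested with the filter), with a median of 0.86 at percentile 99.92. Of 57 alcohol and aldehyde dehydrogenases genes, 9 rose and 0 fell (10 and 0 adjusted over the list alone, 2 and 0 of 26 tested with the filter), with a median of 0.97 at percentile 96.0. Of 77 mobile elements genes, 25 rose and 0 fell (29 and 0 adjusted over the list alone, 9 and 0 of 58 tested with the filter), with a median of 0.83 at percentile 99.95. The 9 called with the filter include the neighbouring transposases of the run pREL1_0282 to pREL1_0291. Of 47 steroid breakdown and Mce transporters genes, 7 rose and 0 fell (9 and 0 adjusted over the list alone, 2 and 0 of 12 tested with the filter), with a median of 1.45 at percentile 99.57. These 7 were RER_47560 and the neighbouring Mce family genes of the run RER_17250 to RER_17310. Mce family protein RER_47560 rose from 8.47 to 149 TPM. Of 44 fatty acid and mycolic acid synthesis genes, 4 rose and 3 fell (the same adjusted over the list alone, 2 and 1 of 31 tested with the filter), with a median of 0.57 at percentile 79.9. Mycolyltransferase RER_36350, of cell envelope assembly, rose from 16.6 to 166 TPM.

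Proline/betaine transporter RER_37810 fell from 909 to 44.7 TPM (log2 fold change -4.32, SE 0.67, adjusted p = 0.0426), and glycine betaine transporter RER_43710 from 430.2 to 108 TPM. Of 10 trehalose and compatible solutes genes, 0 rose and 3 fell (the same adjusted over the list alone, 0 and 2 of 8 tested with the filter), with a median of 0.01 (-0.46 with other scaling) at percentile 18.8. Glutamate dehydrogenase RER_51250 fell from 193 to 13.8 TPM, WhiB family regulator RER_44750 from 216 to 12.9 TPM and IclR family regulator RER_51280 from 212 to 13.3 TPM. Acyl-CoA dehydrogenase RER_51260 fell from 306 to 4.59 TPM, a call lost with the filter. ATPase RER_04910 and aliphatic amidase RER_04920 fell from 128 and 86.2 TPM to 6.96 and 5.76 TPM, calls lost with the filter (adjusted p = 0.117 and 0.179). Of 6 acetate activation genes, 0 rose and 0 fell (the same adjusted over the list alone, limma, with 1 at an unadjusted p under 0.05), with a median of 0.09 (-0.38 with other scaling) at percentile 37.7. Of 10 glyoxylate shunt and gluconeogenesis genes, 1 rose and 1 fell (the same adjusted over the list alone, 0 and 0 of 7 tested with the filter), with a median of -0.01 at percentile 14.7. The 1 that fell was RER_04110, a 2-isopropylmalate synthase admitted by name matching that does other work. Of 16 tricarboxylic acid cycle genes, 0 rose and 0 fell (the same adjusted over the list alone, limma, with 3 at an unadjusted p under 0.05), with a median of -0.00 at percentile 31.6.

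Of 9 propionyl-CoA metabolism genes, 0 rose and 0 fell (the same adjusted over the list alone, limma, with 0 at an unadjusted p under 0.05), with a median of 0.29 (-0.19 with other scaling) at percentile 26.5. Of 41 iron uptake and storage genes, 4 rose and 0 fell (the same adjusted over the list alone, 0 and 0 of 27 tested with the filter), with a median of 0.74 at percentile 82.8. Of 37 nitrogen assimilation genes, 6 rose and 5 fell (7 and 6 adjusted over the list alone, 2 and 1 of 23 tested with the filter), with a median of 0.38 (-0.0862 with other scaling) at percentile 16.6. Of 33 sulfur assimilation genes, 3 rose and 4 fell (the same adjusted over the list alone, 0 and 0 of 18 tested with the filter), with a median of 0.43 (-0.00178 with other scaling) at percentile 2.67. Of 24 sigma factor genes, 5 rose and 1 fell (the same adjusted over the list alone, 0 and 0 of 20 tested with the filter), with a median of 0.52 at percentile 92.6. Of 48 ATP synthase and respiratory chain genes, 7 rose and 1 fell (the same adjusted over the list alone, 1 and 0 of 43 tested with the filter), with a median of 0.60 at percentile 95.3. Of 27 chaperones and proteases genes, 0 rose and 2 fell (0 and 1 adjusted over the list alone, 0 and 0 of 26 tested with the filter), with a median of -0.19 at percentile 5.72. Of 59 ribosomal proteins genes, 1 rose and 1 fell (0 and 1 adjusted over the list alone, 0 and 0 of 58 tested with the filter), with a median of 0.04 (-0.44 with other scaling) at percentile 54.4. Of 32 aromatic compound breakdown genes, 0 rose and 1 fell (the same adjusted over the list alone, 0 and 1 of 12 tested with the filter), with a median of 0.34 (-0.10 with other scaling) at percentile 4.18. Of 6 triacylglycerol and wax ester genes, 2 rose and 0 fell (4 and 0 adjusted over the list alone, 0 and 0 of 3 tested with the filter), with a median of 1.36 at percentile 96.7.

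In limma on log2(TPM + 1), 860 genes passed an adjusted p of 0.05, 605 higher and 255 lower, against 118 higher and 42 lower with the filter and 158 higher and 94 lower with limma-voom on recovered reads. In 626 genes the fitted difference was 4-fold or more, 521 higher and 105 lower (306 and 176 under median-of-ratios scaling, 435 and 220 with the floor subtracted). The median log2 fold change of all genes was 0.45, and median-of-ratios scaling moved it to -0.01 and the split to 293 higher and 308 lower.

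Diesel oil and hexadecane cultures, sampled at the same hour, were compared to set a mixture against a pure alkane. Alkane-1-monooxygenase RER_07460 fell from 4863 ± 51.4 TPM (SD, n = 2) on hexadecane to 1007 TPM on diesel oil (log2 fold change -2.27, SE 0.33). Rubredoxins RER_07470 and RER_07480 and rubredoxin reductase RER_07490 fell, at log2 fold changes of -2.14, -2.17 and -1.96. These 4 calls were lost with the filter (adjusted p = 0.0601, 0.0629, 0.0629 and 0.0732). RER_21620, at 169.9 ± 20.2 and 164 TPM, did not pass. RER_54580 and RER_24030 did not pass, at log2 fold changes of 0.31 and 0.28, whose sign turned under median-of-ratios scaling. Of 34 alkane oxidation genes, 4 rose and 6 fell (the same adjusted over the list alone, 0 and 1 of 21 tested with the filter), with a median of 0.19 (-0.17 with other scaling) at percentile 9.17. Acyl-CoA desaturase RER_21800 fell from 1057 ± 119.8 to 106 TPM (adjusted p = 0.0414), and TetR family regulator RER_04310 from 245 ± 32.5 to 24.4 TPM. Flavin-containing monooxygenase RER_04320 fell from 115 ± 9.88 to 20.2 TPM and MFS transporter RER_04890 from 203 ± 8.23 to 38.0 TPM. Ribosomal protein L31 RER_44010 fell to 8.89 TPM from 186 and 33.7 TPM on hexadecane, a call lost with the filter.

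Drug resistance efflux protein pREL1_0242 rose from 89.5 ± 4.00 TPM (SD, n = 2) on hexadecane to 1159.6 TPM on diesel oil (adjusted p = 0.0404). L-lysine-epsilon aminotransferase RER_21100 rose from 27.3 ± 8.69 to 399.8 TPM (adjusted p = 0.0404). Fatty-acid--CoA ligase RER_50020 rose from 14.0 ± 1.46 to 164 TPM, alcohol dehydrogenase RER_23910 from 38.7 ± 5.70 to 375 TPM and RNA polymerase sigma factor SigB, RER_28040, from 122 ± 0.991 to 648 TPM. Valine dehydrogenase RER_40180 rose from 3.49 ± 2.72 to 319 TPM, and multicopper oxidase RER_03790 from 4.10 ± 4.17 to 113 TPM. Fatty-acid synthase I RER_38730 rose from 10.1 ± 5.97 to 183 TPM, acetate permease RER_45270 from 5.28 ± 4.80 to 97.1 TPM and cytochrome P450 RER_50030 from 23.3 ± 9.98 to 246 TPM. With the filter, RER_40180, RER_03790, RER_38730, RER_45270 and RER_50030 lost their calls (adjusted p = 0.0601, 0.186, 0.0511, 0.0862 and 0.0516).

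Of 57 alcohol and aldehyde dehydrogenases genes, 10 rose and 0 fell (the same adjusted over the list alone, 1 and 0 of 26 tested with the filter), with a median of 0.80 at percentile 100. Of 196 beta-oxidation genes, 22 rose and 1 fell (the same adjusted over the list alone, 1 and 0 of 104 tested with the filter), with a median of 0.59 at percentile 99.98. Of 27 oxidative stress genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone, 0 and 0 of 22 tested with the filter), with a median of 0.94 at percentile 100. Of 6 acetate activation genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone, 0 and 0 of 6 tested with the filter), with a median of 1.33 at percentile 99.85. Of 16 tricarboxylic acid cycle genes, 4 rose and 0 fell (the same adjusted over the list alone, 0 and 0 of 14 tested with the filter), with a median of 1.04 at percentile 100. Malate dehydrogenase RER_41320 rose from 1607 ± 652 to 4882 TPM (SD, n = 2), a call lost with the filter (adjusted p = 0.199). Of 33 sulfur assimilation genes, 2 rose and 8 fell (the same adjusted over the list alone, 0 and 0 of 18 tested with the filter), with a median of 0.02 (-0.21 with other scaling) at percentile 0.02. Sulfate adenylyltransferase subunit RER_37490 fell to 22.9 TPM from 58.7 and 215 TPM, a call lost with the filter (adjusted p = 0.228). Of 41 iron uptake and storage genes, 1 rose and 8 fell (1 and 11 adjusted over the list alone, 0 and 0 of 27 tested with the filter), with a median of -0.15 at percentile 0. Of 59 ribosomal proteins genes, 0 rose and 2 fell (the same adjusted over the list alone, 0 and 0 of 58 tested with the filter), with a median of -0.46 at percentile 0. Of 9 propionyl-CoA metabolism genes, 3 rose and 0 fell (the same adjusted over the list alone, 0 and 0 of 6 tested with the filter), with a median of 0.88 at percentile 97.7. Of 37 nitrogen assimilation genes, 8 rose and 3 fell (the same adjusted over the list alone, 0 and 0 of 23 tested with the filter), with a median of 0.65 at percentile 98.5. Of 48 ATP synthase and respiratory chain genes, 7 rose and 0 fell (10 and 0 adjusted over the list alone, 0 and 0 of 43 tested with the filter), with a median of 0.55 at percentile 99.47.

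Of 10 glyoxylate shunt and gluconeogenesis genes, 1 rose and 0 fell (the same adjusted over the list alone, 0 and 0 of 7 tested with the filter), with a median of 0.70 at percentile 96.1. Of 24 sigma factor genes, 4 rose and 0 fell (the same adjusted over the list alone, 1 and 0 of 20 tested with the filter), with a median of 0.54 at percentile 97.4. Of 27 chaperones and proteases genes, 2 rose and 0 fell (the same adjusted over the list alone, 0 and 0 of 26 tested with the filter), with a median of 0.00 (-0.39 with other scaling) at percentile 11.6. Of 58 multidrug and lipid exporters genes, 5 rose and 0 fell (the same adjusted over the list alone, 1 and 0 of 30 tested with the filter), with a median of 0.24 (-0.0948 with other scaling) at percentile 2.32. Of 77 mobile elements genes, 9 rose and 2 fell (10 and 2 adjusted over the list alone, 1 and 0 of 58 tested with the filter), with a median of 0.39 at percentile 74.2. Of 47 steroid breakdown and Mce transporters genes, 1 rose and 0 fell (the same adjusted over the list alone, 0 and 0 of 12 tested with the filter), with a median of 0.41 at percentile 3.38. Of 10 trehalose and compatible solutes genes, 2 rose and 0 fell (the same adjusted over the list alone, 0 and 0 of 8 tested with the filter), with a median of 0.51 at percentile 86.8. Of 44 fatty acid and mycolic acid synthesis genes, 5 rose and 2 fell (7 and 3 adjusted over the list alone, 0 and 1 of 31 tested with the filter), with a median of 0.44 at percentile 83.6. Of 6 triacylglycerol and wax ester genes, 1 rose and 0 fell (2 and 0 adjusted over the list alone, 0 and 0 of 3 tested with the filter), with a median of 0.71 at percentile 88.2. Of 32 aromatic compound breakdown genes, 0 rose and 0 fell (the same adjusted over the list alone, limma, with 5 at an unadjusted p under 0.05), with a median of 0.35 at percentile 24.1.

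In limma on log2(TPM + 1), 639 genes passed an adjusted p of 0.05, 498 higher and 141 lower, against 26 higher and 6 lower with the filter and 144 higher and 34 lower with limma-voom on recovered reads. In 228 genes the fitted difference was 4-fold or more, 190 higher and 38 lower (128 and 73 under median-of-ratios scaling, 251 and 101 with the floor subtracted). Without hexadecane replicate 1 these were 125 and 95, and without replicate 2 436 and 40. The median log2 fold change of all genes was 0.35, against 0.20 without hexadecane replicate 1 and 0.494 without replicate 2, and median-of-ratios scaling moved it to -0.01 and the split to 180 higher and 160 lower. It moved list medians by -0.39 to -0.23.

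Both comparisons with acetate used its 1 library. In them, 211 genes were higher on both hydrocarbons and 149 lower on both. In 100 simulated sets of unchanged groups sharing that library, lists of the same sizes taken by smallest p shared 154 and 92.9 genes on average and at most 174 and 113, and independent lists of these sizes would share 31.2 and 13.7. With the filter, 49 genes were higher and 30 lower on both, against 26.5 and 15.5 on average and at most 34 and 24 in simulated lists of those sizes. Across genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.742, against 0.576 on average and at most 0.616 in the simulations. Their covariance was 0.838 against 0.494, a difference of 0.344. Without hexadecane replicate 2, whose 5th percentile lay near that of diesel oil, the covariance was 0.659, the difference 0.165 and r 0.602 (at most 0.538 in simulations with 1 hexadecane library). Without replicate 1 they were 1.02, 0.522 and 0.761 (at most 0.541 simulated). With the floor of each library subtracted, r was 0.675 and the covariance 0.908, a value on a scale for which no simulation was run. Acetate could not be split, and the simulations drew from the fitted spread without the floors of the libraries. Part of the excess may therefore come from the shared acetate library or from the raised low values of hexadecane replicate 2 and diesel oil. The simulations also drew each gene independently, whereas genes called the same way often lay side by side, so the simulated maxima may be too low.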

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

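No explanation was tested for the genes in this part, and the fit filtered at 20 TPM and the simulation were chosen after seeing the data. In 9 genes the hydrocarbons moved opposite ways from acetate, lower on hexadecane and higher on diesel oil, by calls of limma in the unfiltered fit. The difference between them is the sum of those folds, so its passing the test without a filter follows from the choice of genes. Simulated unchanged groups sharing the acetate library, without the floors of the libraries, gave 2.68 such genes on average and at most 5 in lists of the same sizes. The simulation drew each gene independently, while some of these 9 genes are neighbours, so its maximum may be too low. Independent lists would give 32.4. With the filter, 0 of them passed in hexadecane vs acetate (8 at an unadjusted p under 0.05, and 0 adjusted with limma-voom), 2 in diesel oil vs acetate and 7 in diesel oil vs hexadecane. The diesel oil vs hexadecane log2 fold changes were 2.40 for RNA polymerase sigma factor SigB RER_28040, 2.39 for AsnC family regulator RER_21090, 3.40 for piperideine-6-carboxylate dehydrogenase RER_21070, 3.86 for L-lysine-epsilon aminotransferase RER_21100, and 3.55 for RER_21080, 4.66 for RER_21720, 3.62 for RER_00880, 3.17 for RER_43170 and 3.03 for pREL1_0220, all 5 of them hypothetical proteins.

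Of these, RER_21070, RER_21080, RER_21090 and RER_21100 lie in consecutive locus tags, and the first and last name enzymes of lysine breakdown. RER_21100 was at 85.2 TPM on acetate, 21.2 and 33.5 TPM on hexadecane and 399.8 TPM on diesel oil. RER_21720 was at 300.4, 90.6, 159.7 and 3063 TPM in the same order. With the filter at 20 TPM the difference no longer passed for RER_43170 (adjusted p = 0.0686) and RER_21080 (adjusted p = 0.0705).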

How the results depend on the processing

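The filter at 20 TPM, the spread without trend, the subtracted floor, their combination and voom were chosen after seeing the data. Counts are given for hexadecane vs acetate, diesel oil vs acetate and diesel oil vs hexadecane, against 685, 860 and 639 genes called and 287, 626 and 228 at 4-fold or more. The number of called genes is the least stable result. It was 130, 160 and 32 with the filter at 20 TPM, 196, 252 and 178 with voom, 34, 0 and 0 with the floor subtracted and the filter, and 0, 0 and 0 with no trend or with the floor subtracted alone. The 34 included RER_07460 (adjusted p = 0.0161) and RER_38730 (adjusted p = 0.0453). At an unadjusted p under 0.05 the floor subtracted alone gave 919, 1099 and 996 and no trend gave 542, 775 and 514. All 130, 160 and 32 genes called with the filter were among the unfiltered calls. The prior degrees of freedom fell from infinite to 4.12 with the filter, 2.42 with no trend and 1.23 with the floor subtracted, where 158 genes became 0 in both hexadecane libraries. At an adjusted p of 0.01 the counts were 486, 547 and 411, and under median-of-ratios scaling 518, 601 and 340.

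At 4-fold or more, a pseudocount of 0.1 gave 449, 962 and 345, voom gave 352 and the subtracted floor 352 for diesel oil vs hexadecane. Without 1 hexadecane library the range was 282 to 514 for hexadecane vs acetate and 220 to 476 for diesel oil vs hexadecane, values with no test. The correlation of the hydrocarbon responses was 0.602 and 0.761 without 1 hexadecane library, and ranged from 0.675 with the floor subtracted to 0.767 with a pseudocount of 0.1 over the other settings. Where no construction is named, the cause was not tested.

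Among the 174 named gene results, 95 lost their call with the filter, 144 with the floor subtracted and the filter, 60 with voom, 22 under median-of-ratios scaling, and 160, all that had one, with no trend or with the floor subtracted alone. Of the fold changes that involve hexadecane, 32 moved by 1 SE of the unfiltered fit or more without replicate 1 (the other 85 by less). Without replicate 2 the same 32 moved as far the other way, which follows from the hexadecane value being the mean of the 2 libraries. Signs turned only for RER_24030 (-0.0804) and RER_54580 (-0.0712) under median-of-ratios scaling, and for RER_21620 (0.0782) and RER_21640 (0.0323) without hexadecane replicate 2, all in diesel oil vs hexadecane and none called. No paired analysis was possible because the groups share fewer than 2 replicate numbers. The count-based tools of the plan were not run, since the tables hold TPM; unique reads were not analysed here.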

Other observations

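The runs and the patterns in this part were chosen after seeing the data, as were the tests of depth, growth on a hydrocarbon, plasmid copy number and sampling hour and the filter and values without the highest genes; the tests of evenness, near-identical copies and coding length were fixed before their results were seen. Genes called the same way lay side by side. Runs of 5 or more consecutive locus tags held 144, 165 and 103 genes in hexadecane vs acetate, diesel oil vs acetate and diesel oil vs hexadecane, and at most 6, 6 and 5 in 1000 permutations of the calls over the genes. With the filter at 20 TPM they held 24, 40 and 0 genes, and at most 0 in each set of permutations.

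The run RER_37810 to RER_37890, with the proline/betaine transporter and ectoine genes, had a median of 598 TPM on acetate and 31.4 and 44.3 TPM (8 of 9 genes called with the filter) on hexadecane. RER_51320 to RER_51370, with urocanate hydratase and imidazolonepropionase of histidine breakdown, went from 149 to 28.5 and 27.5 TPM (4 of 6 genes called with the filter). RER_54810 to RER_54930, which holds acyl-CoA dehydrogenases, went from 110.0 to 15.2 and 28.2 TPM (6 of 13 genes called with the filter). RER_26950 to RER_27050, with isochorismate synthase and a non-ribosomal peptide synthetase, lay higher on hexadecane, at 53.1 and 93.2 TPM against 22.4 TPM (2 of 11 genes called with the filter). The urease run RER_47940 to RER_47990 had medians of 32.6 TPM on acetate and 113 TPM on diesel oil (2 of 6 genes called with the filter).

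Over 546 coding genes chosen for being under 2 TPM on acetate and in hexadecane replicate 1, the median was 4.25 TPM in hexadecane replicate 2 (quartiles 3.30 and 5.46) and 4.62 TPM on diesel oil. Lower depth is argued against for diesel oil, which had 1.18 times the coding reads of acetate. This ratio does not address hexadecane replicate 2, which had the fewest coding reads (6709294, against 12020879 on acetate). Growth on a hydrocarbon as the whole cause is argued against, since the median of hexadecane replicate 1 was 0.271 of that of replicate 2 over genes silent on acetate. An even background, such as reads from genomic DNA, would spread over genes with a coefficient of variation under 0.5 beyond counting error, and a value over 1 in either library was set beforehand as speaking against it. It was 1.51 in hexadecane replicate 2 and 0.881 on diesel oil, but 0.465 and 0.585 without the highest gene of each (RER_09110 and RER_03790), and 0.410 and 0.451 without the highest 5. That bound was passed through 1 gene and does not decide, so an even background, an uneven one and a difference between library preparations stay open, and transfer RNA split the libraries the same way (8.40% and 7.72% of TPM against 3.07% and 2.82%).

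Hexadecane replicate 2 held 15 genes at 50 TPM or more and at least 8 times the highest other library plus 1 TPM, against 0 in replicate 1, 21 on acetate and 16 on diesel oil. RER_40360 was at 1.59 TPM in replicate 1 and 885 TPM in replicate 2, and YrbE family protein RER_09110 at 0.801 and 472 TPM. Reads shared with near-identical copies are argued against, since 0 of these proteins had a copy at 95% identity over 80% of the length, and so is short coding length, with their median at percentile 50.6 of coding genes. No biological explanation was tested, as both libraries carry the same label.

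On pREC1, 29 consecutive genes, pREC1_0022 to pREC1_0050, had a median log2 fold change of -3.69 in hexadecane vs acetate, with 23 of them called lower, 6 with the filter. Plasmid copy number is argued against, since the other 73 pREC1 genes had a median of -0.26, and so are near-identical copies, found for 0 of the block's proteins. The block was also lower on diesel oil, with a median of -2.41; growth on acetate and the later sampling hour both predict this and cannot be told apart in this design.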
